A study of Mus musculus with 5 samples.

How the data were processed

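Chromatin immunoprecipitation with sequencing was done in mouse cultures of neural stem cells (NSC) and of brain tumour stem cells (BTSC). TLX is an orphan nuclear receptor encoded by Nr2e1 and is needed for the maintenance of neural stem cells. Per the labels, cells of either culture carried a retroviral TLX with a 3xTY1 tag, which was precipitated with an antibody against TY1. Acetylation of lysine 27 of histone H3 (H3K27ac), a mark of active promoters and enhancers, was profiled in cells that had not been transduced. The series holds 5 samples with 1 library each: TLX in NSC, TLX in BTSC, H3K27ac in NSC, H3K27ac in BTSC, and a control without antibody from cells with an empty vector. The cell type of that control is not stated beyond cell culture, and no peak list of it was used here. The series holds no TY1 precipitation from cells without tagged TLX, so antibody signal unrelated to TLX cannot be told apart. Per the labels' protocols, fixation took 10 min in 1% formaldehyde and was stopped with 125 mM glycine, chromatin was sheared to about 200 bp, 2 ug of antibody was used, and paired reads of 50 bp were sequenced.

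Per the submitters' processing notes, bcl2fastq 2.17.1.14, Bowtie and ChIPseeker were used with genome build mm10; the peak caller and its settings are not given in the sources used here. The deposited files are 4 peak lists, each called by the authors on 1 library, with narrow peaks for TLX and broad peaks for H3K27ac. Each deposited peak has coordinates, a fold enrichment (a linear ratio over the caller's background), a −log10 p-value, a −log10 q-value and a score. The deposited score is 10 times the −log10 q-value cut to a whole number in nearly all lines. Fold, q and score are the authors' own values per peak and were used to describe, rank or filter peaks within 1 list. Calculations set lists against each other by them in 3 places: rank sums of shared TLX peaks, folds of shared H3K27ac peaks relative to other autosomes, and the pileups and backgrounds solved below. For some peaks the values of both lists are also printed side by side. Read numbers per library are not given in the sources used here, so the depth is unknown. A peak missing from a list therefore means that none was called at that library's depth and enrichment, not that the protein or mark was absent.

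Peak lists were compared by overlap of at least 1 bp. Shares have exact Clopper-Pearson 95% intervals, and ratios of peak numbers have exact conditional binomial intervals; these cover counting error only. With 1 library per group there is no replicate error, no test between groups was made and no p-value is given. Chance overlap came from 1000 random placements of a list within the same chromosomes (100 for annotation), over the span of each chromosome covered by genes or peaks, since no genome sequence was used. Genes were taken from the RefSeq annotation of GRCm38.p6, the assembly of mm10, with 21887 protein-coding genes. That table gives no strand and no exons, so the planned promoter window became 1 kb around either end of a gene, nearest genes were those with the nearest end, and exons, introns and untranslated regions are not distinguished. A gene had TLX when a peak overlapped it or the 10 kb around it. H3K27ac-covered base pairs per gene were counted within 25 kb either side of each gene end.

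The 21 gene lists, with 337 entries that were all found in the annotation, and the rule for named genes were fixed before the data were examined. The rule names the 10 peaks of highest q in each TLX list and the 10 shared TLX peaks of lowest rank sum, the 10 widest peaks of each H3K27ac list, the 10 genes per direction with the largest difference in H3K27ac-covered base pairs, the list members whose class differs between cultures, and Nr2e1. Some genes that the rule names are not reported here, while counts per list cover all members. Each list's count is given beside its percentile among 10000 random gene lists of the same size matched on gene length in 10 classes; for H3K27ac the value ranked is the number of genes in the BTSC class minus the number in the NSC class. These percentiles describe these libraries. Random lists drew genes singly, so neighbouring members of a list, such as those of a Hox cluster, can share 1 peak and are not independent. The list named posterior Hox also holds more anterior Hox genes, such as Hoxa2 and Hoxa3. Alternatives were a stricter q (−log10 q of at least 5), a reciprocal overlap of 50%, summits within 200 bp, lists cut to equal numbers of peaks, a gene end window of 2.5 kb, joining of peaks within 1 kb, the gene with the nearest end for TLX, and covered base pairs per chromosome. Leaving out chromosomes 1 and 6, a stricter form of the gene classes, placement within H3K27ac regions, random lists matched on H3K27ac, lists without Nr2e1, and equal numbers of peaks without genes on chromosomes 1 and 6 were added after the data had been seen. The 15 motifs fixed beforehand were not run here, since they need the genome sequence.

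For the TLX lists, a whole fragment pileup and a background were solved from the deposited fold and p of each peak, assuming a Poisson tail and 1 added to both; this was used for Nr2e1 and for the additional observations.

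Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The code was tested on simulated data and by brute force: overlap calls matched for 1434 of 1434 BTSC TLX peaks, the pileup and background of 2000 of 2000 simulated peaks were recovered, a planted list of genes reached percentile 100, and 4 of 60 random lists fell outside percentiles 5 to 95.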

Results

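The series asks where TLX binds and which regions carry H3K27ac in normal and tumour neural stem cells in culture. Peaks were called for 4 libraries, 1 per group, so every value below describes a single library and has no replicate check. The TLX list of NSC had 7458 peaks with a median width of 609 bp, and that of BTSC had 1436 peaks with a median width of 534 bp. The H3K27ac lists were nearly equal in number, with 31266 peaks covering 68.5 Mb in NSC and 31597 peaks covering 74.1 Mb in BTSC. All positions are in mm10.

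The 10 leading TLX peaks of either list overlapped a peak of the other, and the NSC list was 5.19 times as long. The strongest site was a peak inside Psmf1, which encodes an inhibitor of the proteasome, at chromosome 2, 151740819 to 151741923, with a fold of 72.3 in the NSC list; it ranked 2 in the BTSC list with a fold of 52.6. Further leading sites in both lists lay inside Thsd4 (chromosome 9, 60311472 to 60312338), a gene of the extracellular matrix, inside Serinc5, and inside Sparcl1 (chromosome 5, 104110069 to 104110947), a secreted glycoprotein of astrocytes. Their folds in the NSC list were 33.9, 22.9 and 23.5. The 10 leading NSC peaks all overlapped a BTSC peak, among them peaks inside Mrps28 and Rab31, a peak 75432 bp from an end of Tnfsf11, a peak 16933 bp from Mturn and a peak 366632 bp from Tcf4, which encodes a partner of proneural transcription factors. Leading BTSC peaks also lay in Bag1, a co-chaperone, 8901 bp from Bahcc1 and 36951 bp from Atp6v1g3, the last on chromosome 1. Of the leading peaks, 1 of 10 in NSC and 3 of 10 in BTSC had a fold under 2 despite a high q: a peak at 98666659 on chromosome 2, more than 1 Mb from Lrrc4c, and peaks at 3000509 and 3023555 near the start of chromosome 9, where Alkbh8 was the nearest gene.

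Of the BTSC TLX peaks, 1174 of 1436 overlapped an NSC TLX peak, which is 81.8% (95% interval 79.7 to 83.7) against a mean of 0.388% for random placements. Conversely 1176 of the 7458 NSC peaks overlapped a BTSC peak, 15.8% (14.9 to 16.6) against 0.0742%. When BTSC peaks were placed at random within BTSC H3K27ac regions, a mean of 10.8% met an NSC TLX peak and the highest of 1000 placements gave 13.0%. The share of NSC peaks found in BTSC was 58.0% (54.4 to 61.6) in the top 10% by q and 2.01% (1.13 to 3.299) in the lowest 10%. With the NSC list cut to its 1436 strongest peaks, 44.7% of either list overlapped the other, so the share depends on the number of peaks taken.

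**Figure D1:**
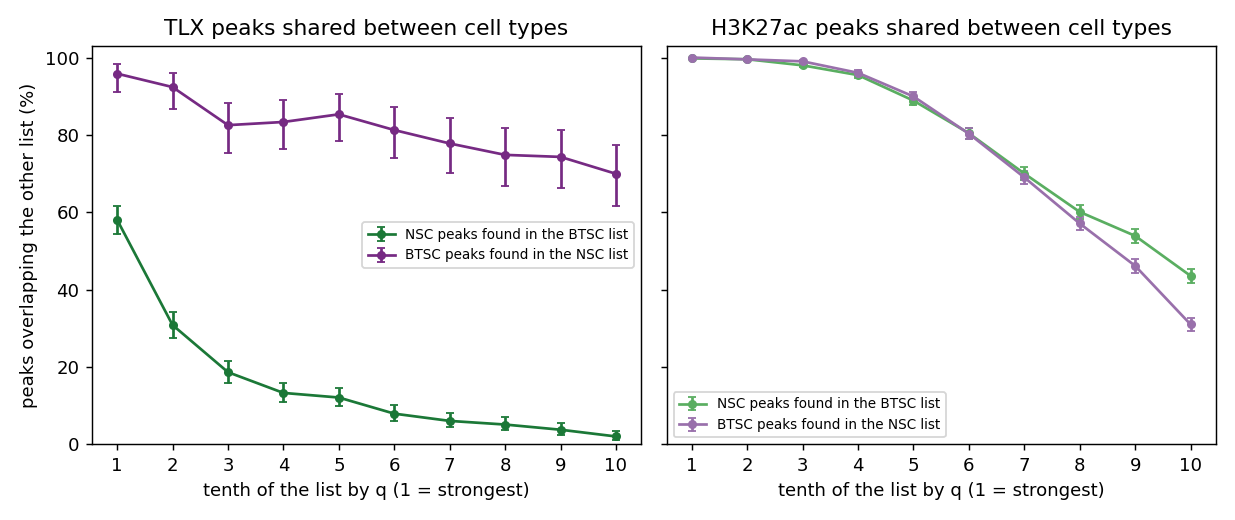
Share of peaks (percent, y axis) that overlapped the list of the other culture, in 10 equal classes of each list ranked by q (x axis, 1 is strongest), for TLX on the left and H3K27ac on the right; bars are exact 95% intervals. NSC TLX peaks went from 58.0% in the top 10% to 2.01% in the lowest, whereas BTSC TLX peaks went from 95.8% to 69.9%.

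Genes of neural stem cells carried TLX peaks in both cultures more often than random genes of like length. Of the 18 genes of that list, 14 had a TLX peak in NSC, against a mean of 4.32 in random lists (percentile 100), and 8 had one in BTSC, against 0.866 (percentile 100). With the NSC list cut to the number of BTSC peaks, 4 of them had a TLX peak in NSC (percentile 99.7), fewer than the 8 in BTSC. Egfr, Hes1, Notch1, Slc1a3, Sox1 and Sox2 were among those with peaks in both lists, Nes, Vim, Fabp7, Hes5, Msi1, Pax6 and Sox9 in the NSC list only, and Nr2e1 in the BTSC list only. Without Nr2e1, where the background was raised as given below, the BTSC count was 7 of 17 (percentile 100). In the Notch pathway, which keeps progenitors undifferentiated, 9 of 16 genes had a peak in NSC (percentile 99.7) and 6 in BTSC (percentile 100), with Hes1, Jag1, Lfng, Notch1 and Notch2 in both and Heyl in BTSC only. Of 15 genes reported as TLX targets, 8 had a peak in NSC (percentile 99.4) and 4 in BTSC (percentile 99.8): Gfap and Mir9-2 were among those in both, Ccnd1, Plce1, Tet3 and Wnt7a in the NSC list only, and Cdkn1a, encoding the cell cycle inhibitor p21, had no peak in either. With equal numbers of peaks the counts of these targets were 4 in NSC (percentile 99.8) and 4 in BTSC. Among TLX cofactors and related nuclear receptors the counts were 12 of 16 in NSC (percentile 99.995) and 3 in BTSC (percentile 96.9). Rcor1 and Rxra were in both, and Hdac5, Kdm1a, Bcl11a, Nr2f1 and Nr2f2 in NSC only. Nr2e1 was in BTSC only, and without it the BTSC count was 2 of 15 (percentile 87.2). Over all protein-coding genes, 5430 had a TLX peak in NSC and 1120 in BTSC, 1005 of them in both and 115 in the BTSC list only.

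Most signalling and lineage lists had more genes with TLX in the longer NSC list, and for most this order was not kept with equal numbers of peaks. The Wnt pathway had 11 of 18 genes with TLX in NSC (percentile 99.5) and 3 in BTSC (percentile 91.4), with Axin2, Tcf7l1 and Wnt5a in both and Wnt7b, Lgr5 and Tcf7l2 in NSC only. The Hedgehog pathway had 8 and 3 of 12 (percentiles 99.1 and 96.9), with Boc, Gli2 and Gli3 in both and Ptch1 and Smo in NSC only. Forebrain patterning genes had 8 and 2 of 15 (percentiles 99.8 and 94.7), with Dmrta2 among those in both. Astrocyte genes had 7 and 4 of 14 (percentiles 97.4 and 99.7), with Gfap, Glul, Slc1a2 and Aldh1l1 in both. Genes of the oligodendrocyte lineage had 6 and 2 of 14 (percentiles 94.7 and 92.4), with Olig1 and Olig2 in both. BMP and TGF-beta genes had 10 and 3 of 19 (percentiles 97.6 and 90.8), cell cycle inhibitors and tumour suppressors 6 and 3 of 15 (percentiles 88.6 and 97.4; Cdkn1b and Nf1 among those in both), receptor tyrosine kinases and ligands of glioma 7 and 2 of 18 (percentiles 74.0 and 76.8; Egfr and Igf1r in both), and mesenchymal glioblastoma genes 9 and 1 of 20 (percentiles 95.3 and 47.6; Cebpd in both). Proliferation genes had 7 and 0 of 18 (percentiles 94.4 and 23.0), with Myc, Ccnd1 and Ccnd2 in the NSC list only and 0 and 0 with equal numbers of peaks, and posterior Hox genes 6 and 0 of 23 (percentiles 77.4 and 21.6), all in the Hoxa cluster on chromosome 6. Neuron genes had 3 and 0 of 16 (percentiles 12 and 15.03), interferon and antigen presentation genes 1 and 0 of 18 (percentiles 5.38 and 25), microglia genes 1 and 0 of 12 (percentiles 9.33 and 27.9), endothelial genes 1 and 0 of 12 (percentiles 1.77 and 16.8), and genes of other tissues 0 and 0 of 16 (percentiles 2.1 and 29.5). Housekeeping genes had 5 and 1 of 12 (percentiles 96.1 and 79.9), the first of them above those of the oligodendrocyte and mesenchymal lists; with random lists matched also on H3K27ac it was 73.6. With equal numbers of peaks, 1064 genes had TLX in NSC against 1120 in BTSC, and 586 had it in the BTSC list only. Notch genes in NSC were then 3 (percentile 98.3), fewer than the 6 in BTSC, and TLX cofactor genes 4 (percentile 99.6), against 3 in BTSC. BTSC then also had more in the astrocyte list (4 against 2), cell cycle inhibitors (3 against 1), BMP and TGF-beta genes (3 against 2), forebrain patterning genes (2 against 1), receptor tyrosine kinases and ligands (2 against 1) and mesenchymal genes (1 against 0). NSC had more among Wnt and Hedgehog genes (4 against 3 each) and housekeeping genes (2 against 1), oligodendrocyte genes were level at 2, and the remaining lists of this paragraph had 0 in both. With genes on chromosomes 1 and 6 also left out, the Wnt list (2), BMP and TGF-beta genes (2), TLX cofactors (3) and housekeeping genes (1) were level, and reported TLX targets had 3 in NSC against 4 in BTSC.

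**Figure D2:**
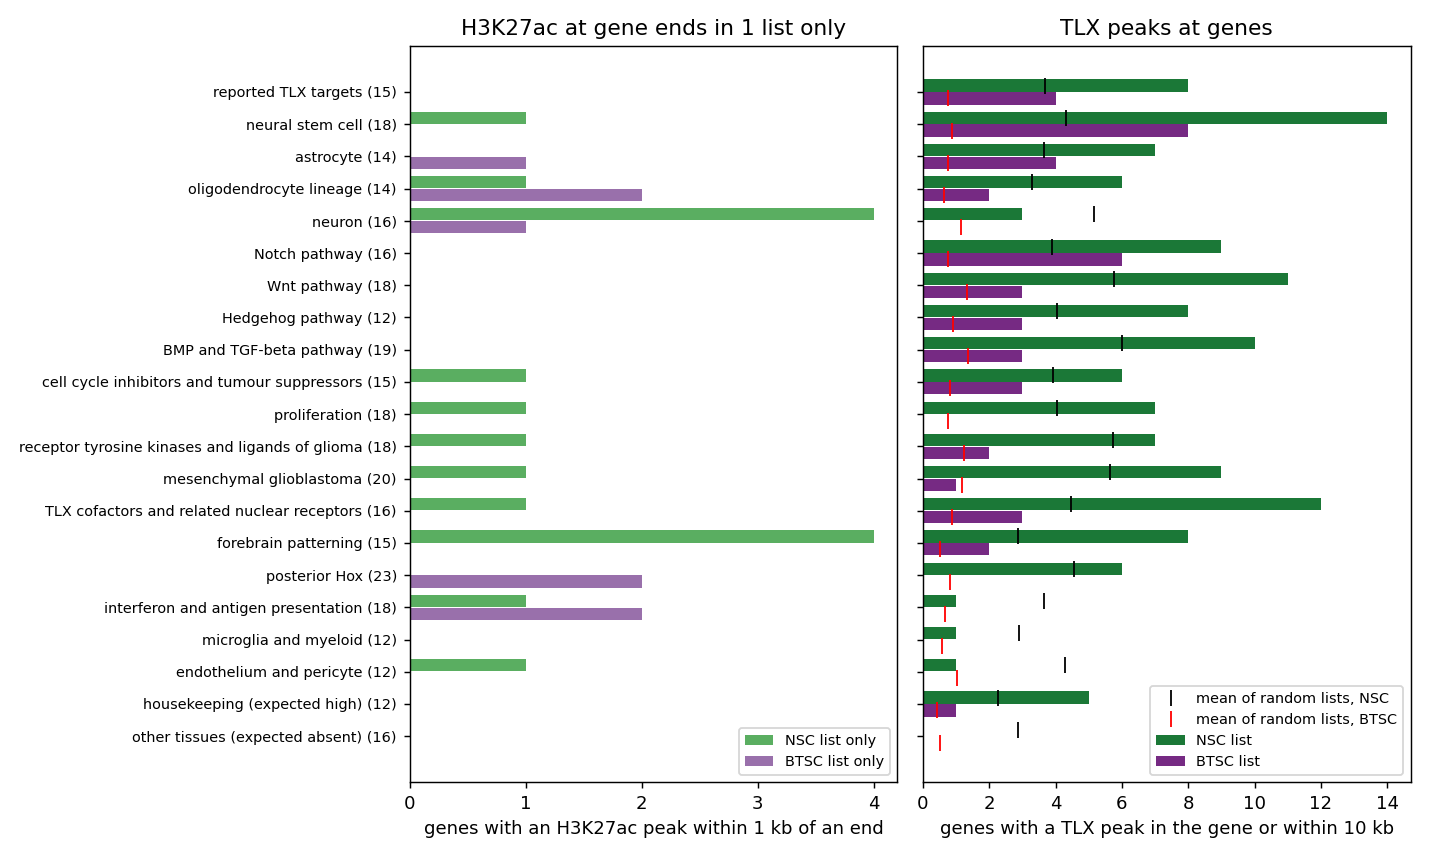
Left, number of genes per list (x axis; list size in brackets on the y axis) with H3K27ac within 1 kb of a gene end in the NSC or the BTSC list only; right, number with a TLX peak in the gene or within 10 kb, with the mean of random lists matched on gene length as ticks. Neural stem cell genes had 14 and 8 of 18 with TLX in NSC and BTSC (4 and 8 with equal numbers of peaks), and forebrain patterning genes had 4 with H3K27ac in the NSC list only.

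The H3K27ac landscapes of the 2 cultures were largely shared at strong regions and differed at particular developmental genes. Of NSC peaks, 79.0% (78.5 to 79.4) overlapped a BTSC peak, and of BTSC peaks 76.8% (76.3 to 77.3) overlapped an NSC peak, against 5.62% and 5.54% at random. Overlap was 99.8% in the top 10% of the NSC list and 43.5% in the lowest, and 100% and 30.99% in the BTSC list. The lists shared 51.0 Mb, which is 55.7% of the base pairs covered by either. The widest domains recurred between cultures: domains inside Lrig1, a negative regulator of receptors of the EGF family (59694 bp in NSC and 62872 bp in BTSC), inside Ptn, a secreted growth factor (45044 and 60392 bp), inside Xylt1, which starts glycosaminoglycan chains (48542 and 112626 bp), inside Myt1 (41518 and 57079 bp), and over the microRNA genes Mir9-1 (52772 and 53065 bp) and Mir9-3 (43315 and 59305 bp) were among the 10 widest of both lists. The remaining wide domains of NSC lay inside Prex1, Npas3, Acss1 and the Pcdhg cluster, and those of BTSC inside Map4k4 on chromosome 1, the GABA transporter gene Slc6a11 and Maml2, which encodes a Notch coactivator, and over Mirlet7b and Mirlet7c-2 on chromosome 15.

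Six3, Ccnd2 and Wnt7a were among the genes with more H3K27ac in NSC, and Chd7 and Qk among those with more in BTSC. Six3, a homeobox gene of the anterior forebrain, had 15419 covered bp in NSC and 0 in BTSC. Ccnd2, encoding a D-type cyclin, had 29284 and 10368 bp, the ligand gene Wnt7a 32876 and 16270 bp, and Fbln2 38126 and 18774 bp; these last 3 are on chromosome 6, which had fewer H3K27ac peaks in BTSC throughout. Clip2 (40252 and 15582 bp), Nrxn2 (43711 and 21242 bp), Iffo2, Col5a3, Rtkn2 and Hdac5 (28446 and 13254 bp) completed the 10 largest differences. In the other direction stood Rpn2 (21906 bp in NSC and 65340 bp in BTSC), the chromatin remodeller gene Chd7 (14753 and 52074 bp), Qk, an RNA-binding protein of glia (50148 and 80820 bp), Grk3 and Lpcat1. Arhgef4, Trp53bp2, Mapkapk2 and Itpkb (8656 and 37418 bp) were also among these 10 and lie on chromosome 1, which had more H3K27ac peaks in BTSC. Egfr, chosen after its values were seen, had 9267 covered bp in NSC and 26599 bp in BTSC, whereas Fgfr1 (18272 and 10589 bp), Vegfa (7249 and 3443 bp) and Pdgfa (5247 and 2613 bp) of the same list had less in BTSC. These differences rest on the covered length in 1 library per culture.

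By called peaks at gene ends, forebrain patterning genes stood apart from the other lists. H3K27ac lay within 1 kb of an end of 10861 protein-coding genes in both lists, of 574 in the NSC list only and of 457 in the BTSC list only. Of 15 forebrain patterning genes, 4 were in the NSC class, namely Dlx1, Gsx1, Lhx2 and Six3, and 0 in the BTSC class, a difference at percentile 0.02 of random lists, although Lhx2 had more covered bp in BTSC (5820) than in NSC (2426). Emx2, Otx1, Dmrta2, Dlx2, Nr2f1 and Nr2f2 were among those with H3K27ac in both. Covered bp of the list went both ways. Otx1 had 11861 bp in NSC and 19426 in BTSC, and Nr2f1 had 18671 and 22379. Emx2 had 11245 and 4706, and Dlx1 of the NSC class had 2962 and 1873. Neuron genes had 4 in the NSC class (Dcx, Elavl3, Neurod1 and Syt1) and 1, Neurog2, in the BTSC class (percentile 0.535); Elavl3 had 4666 covered bp in NSC and 5910 in BTSC. Neuron genes in the NSC class were 1 with a stricter q in both lists, against 1 in the BTSC class (percentile 55.8). They were 0, against 1, when a peak had to pass the stricter q with no peak at all in the other list (percentile 93.0). The list named posterior Hox had 2 of its more anterior members in the BTSC class (percentile 97.2). These were Hoxa2 and Hoxa3, which pattern the hindbrain, though they lie on chromosome 6 and are neighbours. The BTSC class had 0 with a window of 2.5 kb, 3 with a stricter q in both lists (percentile 99.7) and 2 when a peak had to pass the stricter q with none in the other list (percentile 99.1). Hoxa4, Hoxa5 and Hoxa7 were in both, and 18 of 23, among them Hoxa9 and Hoxa10, in neither.

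Other lists differed by a few genes each. In the oligodendrocyte lineage, Nkx2-2 was in the NSC class, with 13645 covered bp against 878, and Myrf was among those in the BTSC class (percentile 88.3 for the list), while Olig1, Olig2, Sox10 and Pdgfra had H3K27ac in both. Of astrocyte genes, Aldh1l1 was in the BTSC class (percentile 87.9) and 10 of 14 in both. The surface marker gene Prom1 was the 1 of 18 neural stem cell genes in the NSC class (percentile 17.8), with 14 in both. The NSC class also held Cdkn1c (cell cycle inhibitors and tumour suppressors, percentile 16.8), Ccnd2 (proliferation, 17.1), Pdgfa (receptor tyrosine kinases and ligands, 19.4), Bcl11a (TLX cofactors, 16.1) and Flt1 (endothelium, 15.6). The mesenchymal glioblastoma list stood at percentile 20.1. Of interferon and antigen presentation genes, H2-D1 was in the NSC class, with 4479 covered bp in NSC and 5401 in BTSC, and Ifit1 and Irf9 in the BTSC class (percentile 87.4). No member differed in class between cultures among reported TLX targets, Notch, Wnt, Hedgehog, BMP and TGF-beta, microglia, housekeeping or other-tissue genes. H3K27ac lay at 12 of 12 housekeeping genes, at 1 of 12 microglia and myeloid genes (Cd68), at 1 of 12 endothelial genes and at 0 of 16 genes of other tissues. Where a gene of a class had to pass the stricter q in its list and lack any peak in the other, 303 genes remained in the NSC class and 218 in the BTSC class.

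TLX peaks lay in acetylated chromatin in both cultures. In NSC, 6830 of 7458 TLX peaks (91.6%, 90.9 to 92.2) overlapped an H3K27ac peak of NSC, and in BTSC 1339 of 1436 (93.2%, 91.8 to 94.5) overlapped one of BTSC, against 3.72% and 3.85% at random. The overlap with the other culture's H3K27ac was 88.1% and 86.8%. Of the leading TLX peaks, those inside Thsd4 and near Mturn, Atp6v1g3, Lrrc4c and Alkbh8 lay outside H3K27ac of both cultures, and the Bag1 peak lay in H3K27ac of BTSC alone. The peaks near Lrrc4c and Alkbh8 were those with a fold under 2, and no filter for regions of artefact signal was applied here. Of the 6282 TLX peaks in the NSC list only, 85.3% (84.4 to 86.2) lay in regions acetylated in both lists and 6.69% in regions of the NSC list alone. Of the 262 TLX peaks in the BTSC list only, 74.4% lay in regions of both lists, 16.8% (12.5 to 21.9) in regions of the BTSC list alone and 1.15% in regions of the NSC list alone. These splits were not repeated without chromosomes 1 and 6, and chromosome 1 held 20.7% of all BTSC TLX peaks. TLX peaks overlapped 24.0% of the NSC H3K27ac peaks found in both lists and 5.79% of those in the NSC list alone; in BTSC these shares were 4.88% and 1.32%. Peaks found in 1 list alone were narrower, with medians of 938 bp in NSC and 940 bp in BTSC against 1767 and 1808 bp for shared peaks.

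Relative to genes, 31.7% (30.6 to 32.8) of NSC TLX summits and 23.0% (20.8 to 25.2) of BTSC TLX summits lay within 1 kb of a gene end, against 3.11% and 3.02% at random. A further 39.3% and 42.3% lay inside a gene, against 38.9% at random for either, and 29.0% and 34.7% between genes, against 58.0% and 58.1%. For H3K27ac midpoints, 27.3% in NSC and 25.7% in BTSC were within 1 kb of a gene end, against 3.14% and 3.11% at random, and 44.6% and 49.2% further inside a gene, against 38.7% for either.

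Nr2e1, the gene of TLX itself, at chromosome 10, 42561963 to 42583590, had no TLX peak within 100 kb in NSC and 6 in BTSC. The BTSC peaks ran from 42501759 to 42592640, with folds from 2.86 to 5.73. H3K27ac marked the gene end in both cultures, by a peak of 3071 bp at 42581954 in NSC and of 7654 bp at 42577911 in BTSC, and within 100 kb there were 4 and 9 H3K27ac peaks. The region at 42500833 to 42503748 held the highest −log10 q of the whole BTSC H3K27ac list, 516, while the overlapping NSC peak had 92.3 in its own list. The retroviral TLX was carried by the cells of the TLX libraries and not by those of the H3K27ac libraries. The background solved from the deposited fold and p at the 6 BTSC TLX peaks was 2.29 to 3.65 times the lowest common value of that list. For NSC none could be solved there, since no TLX peak was called. Whether a raised background kept NSC peaks around Nr2e1 from being called was not tested.

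**Figure D3:**
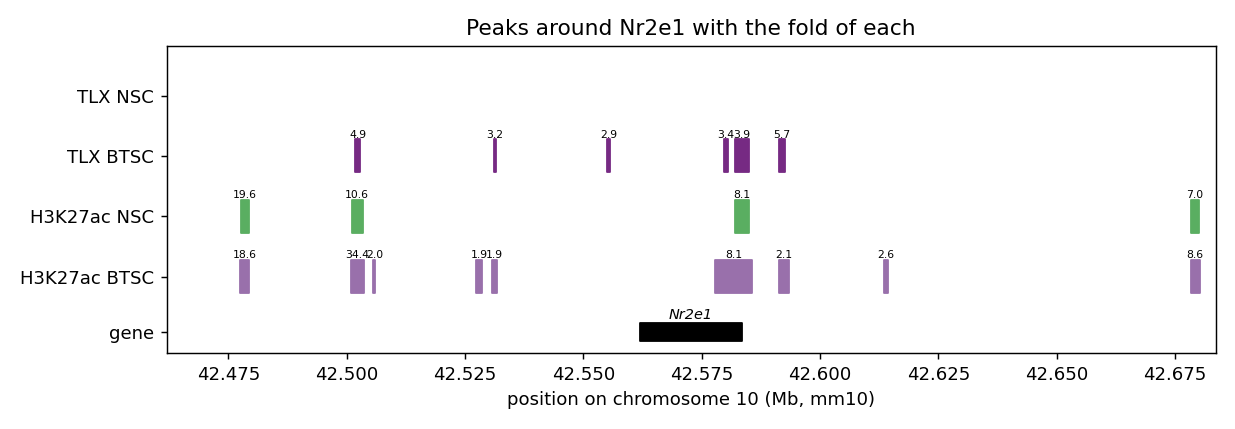
Peaks of the 4 lists (rows) within 100 kb of Nr2e1 on chromosome 10 (x axis, Mb, mm10), drawn to scale with the authors' fold above each peak; folds compare within a row only. The TLX list of NSC had 0 peaks there and that of BTSC had 6.

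Chromosomes 1 and 6 departed from the rest in both marks. On chromosome 1 the ratio of BTSC to NSC peak numbers was 1.35 (1.28 to 1.44) for H3K27ac, from 2662 and 1965 peaks, and 0.644 (0.555 to 0.747) for TLX, from 297 and 461 peaks. On chromosome 6 it was 0.806 (0.754 to 0.861) for H3K27ac, from 1609 and 1997 peaks, and 0.0975 (0.0759 to 0.124) for TLX, from 75 and 769 peaks. The other 17 autosomes had ratios between 0.935 and 1.045 for H3K27ac (median 1.01) and between 0.130 and 0.223 for TLX (median 0.171). Chromosome 1 thus held 20.7% of BTSC TLX peaks and 6.18% of NSC TLX peaks. Of genes with H3K27ac at an end in 1 list only, chromosome 1 had 13 in the NSC class and 41 in the BTSC class, chromosome 6 had 42 and 23, and all others had 519 and 393. In covered base pairs the H3K27ac ratio on chromosome 1 was 1.66, where the other 17 autosomes had 0.960 to 1.15 (median 1.08).

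**Figure D4:**
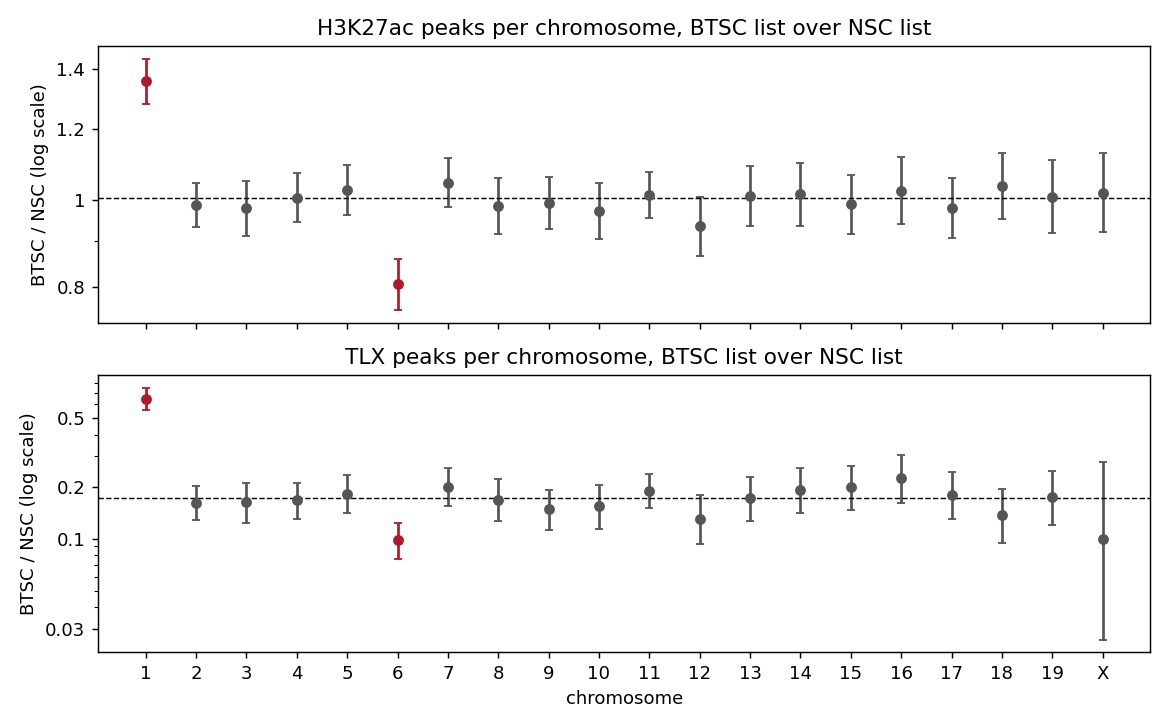
Ratio of BTSC to NSC peak numbers per chromosome (y axis, log scale) for H3K27ac above and TLX below, with exact 95% intervals; the dashed line is the median of the 17 autosomes other than 1 and 6, which are in red. Chromosome 1 stands at 1.35 and 0.644 and chromosome 6 at 0.806 and 0.0975.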

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

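All tests in this part were chosen after the result was seen, except those of shared peak folds on chromosomes 1 and 6, whose outcome was not known when they were set. The deposited fold and p of a TLX peak can be solved together for a whole fragment pileup and a background if the caller used a Poisson tail and added 1 to both; the solution exists within 0.002 of −log10 p for 99.96% of NSC and 99.86% of BTSC TLX peaks, against 3.80% and 2.40% of 500 peaks with shuffled p. The background so recovered is taken to reflect the control library, whose use by the caller is not stated. Of 139 shared peaks with a background of at least 1.2 floors in NSC, 108 (77.7%) had one in BTSC, against 45 of the 1031 others. This does not settle the source, since a background drawn from each TLX library itself could also be raised at the same sites. The lowest common value of the background, the floor, was 4.23 in NSC and 3.37 in BTSC. At the BTSC TLX peaks around Nr2e1 the background reached 3.65 times the floor. It lay at least 5% above the floor at 61.3% of BTSC TLX peaks on chromosome 1 and at 38.7% on chromosome 6, where the 17 other autosomes had 13.8% to 25.5%.

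The first pattern is the excess of BTSC peaks on chromosome 1 and of NSC peaks on chromosome 6. A lower depth or another threshold of 1 H3K27ac library would move all chromosomes alike, whereas the ratio of 1.35 on chromosome 1 lay above the range of the 17 others. A change at a subset of sites would leave the shared H3K27ac peaks alone, but their median fold relative to other autosomes was 1.23 times as high in the BTSC list as in the NSC list on chromosome 1 and 0.838 times as high on chromosome 6, with 0.949 to 1.04 on the others. On chromosome 1 the relative fold was 0.856 in NSC, the lowest autosome of that list, and 1.049 in BTSC. On chromosome 6 it was 1.038 in NSC and 0.870 in BTSC, the lowest autosome there. Extra copies of chromosome 1 in the BTSC culture and of chromosome 6 in the NSC culture remain open. Fewer copies in the other culture remain open too, since a ratio between the lists cannot tell a gain from a loss. Either would go with the windows of 20 Mb. Of these, 10 of 10 lay above the median ratio on chromosome 1 and 8 of 8 below it on chromosome 6. A change of chromatin over a whole chromosome was not tested. The control may carry extra copies too, since 58.1% of NSC TLX peaks on chromosome 1 and 34.2% on chromosome 6 had a raised background, above the 23.0% that was the highest among the other autosomes.

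The second pattern is the shorter TLX list of BTSC. If the floors track the depth of the TLX libraries, which was not checked, the BTSC library had 0.797 times the coverage of the NSC one. On that condition depth as the whole cause is argued against: of 4773 NSC peaks that would still clear the BTSC threshold by a margin of 3 in −log10 p at that coverage, 22.2% (20.99 to 23.4) were called in BTSC. Loss of the called H3K27ac peak as the main cause is argued against as well, since 6.69% of the NSC TLX peaks missing from BTSC lay in H3K27ac of the NSC list alone. Weaker H3K27ac at peaks called in both lists was not tested, and the H3K27ac libraries came from cells that had not been transduced. A lower enrichment over background in the BTSC library remains open. The share of NSC peaks called was 28.8 times as high in the top 10% as in the lowest. That ratio cannot single out enrichment, since lower depth or occupancy would also lose weak peaks first. At 1170 shared peaks the median pileup was 8.51 floors in NSC and 7.12 in BTSC, and 71.1% were higher in NSC. A real difference in TLX occupancy, or in the amount of tagged TLX, between the cultures would give the same values and stays open, untested.

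The third pattern is the group of TLX peaks around Nr2e1 in BTSC. The lowest background at the 6 peaks was 2.29 times the floor, but the folds of 2.86 to 5.73 are already taken over it, so this does not decide whether TLX occupancy is the source. Extra copies of this segment in the control library may be present, which alone would lower the folds, since at 6 of the 6 peaks the background lay above the 99th percentile of the other BTSC TLX peaks, 1.69 floors. Relative to the median of peaks of like p, the H3K27ac folds in NSC were 0.639 and 0.613 at 42501035 and 42581954 and 0.966 and 1.03 at 42477599 and 42678413; in BTSC they were 0.557 to 0.836 at the 6 peaks from 42505633 to 42613472, but also 0.845 at the more distant 42409514, while the BTSC peak at 42500833, the highest of its list, has no peers of higher p. Whether the BTSC culture holds more copies than the control, whether TLX is bound there, and where such copies would come from, was not tested.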

How the results depend on the processing

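Of the values that answer a comparison, 41 stayed within their interval or 1.5 times their count and 35 moved, and of single lists and genes 47 stayed and 9 moved. Some that stayed could not move, such as BTSC TLX values with equal numbers of peaks, where that list was not cut. Counts that stayed could also hold other genes. With a −log10 q of at least 5 in both lists, 594 genes had H3K27ac in NSC only and 448 in BTSC only. Of the 574 and 457 genes of the main setting, 303 and 218 were among them. The settings without chromosomes 1 and 6, with a peak in 1 list against none in the other, with random lists matched on H3K27ac, and with lists without Nr2e1 were chosen after the data had been seen. The cause was not tested unless named. A reciprocal overlap of 50%, stricter by construction, gave 67.2% of BTSC TLX peaks in NSC, 12.9% of NSC in BTSC, and 60.5% of BTSC and 61.1% of NSC H3K27ac peaks in the other list; summits within 200 bp gave 69.2% and 13.3% for TLX. Equal numbers of peaks gave 44.7% for TLX in either direction, 77.4% of BTSC H3K27ac peaks in NSC, 86.1% of NSC TLX peaks in H3K27ac, and 1064 genes with TLX in NSC, 534 in both and 586 in BTSC only, since the NSC TLX list was cut, while for H3K27ac the BTSC list was; NSC then had fewer genes with TLX than BTSC, the other way round from the full lists, over all genes (1064 against 1120) and in the neural stem cell (4 against 8), Notch (3 against 6), astrocyte (2 against 4), cell cycle inhibitor (1 against 3), BMP and TGF-beta (2 against 3), forebrain patterning, receptor tyrosine kinase (1 against 2 each) and mesenchymal lists (0 against 1), and proliferation and posterior Hox genes had 0 in both. A −log10 q of at least 5 in both lists gave 80.8% of BTSC and 82.9% of NSC H3K27ac peaks shared, 84.3% of NSC and 84.6% of BTSC TLX peaks in H3K27ac, where fewer H3K27ac regions were left, and 29.4%, 20.3%, 38.7% and 35.9% of peaks within 1 kb of a gene end for TLX in NSC and BTSC and H3K27ac in NSC and BTSC. The window of 2.5 kb, wider by construction, gave 39.0%, 28.8%, 33.6% and 32.9% in the same order. TLX summits inside H3K27ac gave 90.5% in NSC. Without chromosomes 1 and 6, sharing was 85.2% of BTSC and 14.6% of NSC TLX peaks and 77.9% of BTSC H3K27ac peaks, and 27.9% of NSC and 26.6% of BTSC H3K27ac peaks lay within 1 kb of a gene end. Genes with H3K27ac in 1 list only were 303 for NSC and 218 for BTSC where the peak had to pass the stricter q against no peak at all; neuron genes were then 0 against 1, the other way round from 4 against 1, at percentile 93.0. In covered base pairs, the BTSC to NSC ratio was 1.66 for H3K27ac on chromosome 1, against 0.960 to 1.15 on the 17 other autosomes. For TLX on chromosome 6 it was 0.0707. Random lists were matched also on whether H3K27ac lay at a gene end in either list, but not on its covered length. Neural stem cell genes with TLX then stood at percentiles 99.99 in NSC and 100 in BTSC, and Notch genes at 98.1 and 99.995. Cell cycle inhibitors in NSC were put at 55.8, proliferation genes at 71.4 and housekeeping genes at 73.6. Posterior Hox genes in NSC rose to 97.9, but those with TLX are neighbours in the Hoxa cluster, where 1 peak can count for more than 1 gene. Joining H3K27ac peaks within 1 kb changed nothing because the smallest gap in either list was 1629 bp. The motif results and their alternatives were not run. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Read numbers are not given, and a peak absent from the shorter TLX list may be below its threshold. If the floors track depth, which was not checked, depth as the whole cause is argued against by the 22.2% called among NSC peaks that would clear the threshold at that coverage.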

Other observations

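The values in this part were looked up after the data had been seen, and each describes 1 library per group. All 3 genes of the neural microRNA miR-9, which acts in a feedback loop with TLX, lay in wide H3K27ac domains of both cultures. Mir9-1 (chromosome 3, 88215598 to 88215686) and Mir9-3 (chromosome 7, 79505264 to 79505353) had 1 TLX peak each within 3 kb in NSC and 0 in BTSC, whereas Mir9-2 (chromosome 13, 83738814 to 83738885) had 3 in NSC and 2 in BTSC. Among the strongest 10% of NSC TLX peaks, 4 of the 37 in regions acetylated in the NSC list alone were called in BTSC, 10.8% (3.03 to 25.4), compared with 358 of the 590 in regions acetylated in both, 60.7% (56.6 to 64.6), and 29 of the 41 in regions of the BTSC list alone, 70.7% (54.5 to 83.9). Of the 78 in neither H3K27ac list, 53.8% were called in BTSC. These shares were not computed without chromosomes 1 and 6, where both marks departed from the rest.

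Runs of at least 8 consecutive H3K27ac peaks without a counterpart numbered 14 in NSC, with 123 of 6579 such peaks, and 7 in BTSC, with 63 of 7328; the number expected by chance was not computed. The longest run in NSC had 11 consecutive peaks across the region of the axon guidance receptor gene Robo1 (chromosome 16, 70608148 to 73036788), followed by 10 across Bcl11a (chromosome 11, 24047885 to 25914883) and 9 each in stretches with Dpp10, with Tlr4 and Brinp1, with Tusc3 and Msr1, with Tmem132e and Cct6b, with Grid1 and 2 other genes, and with 15 genes of and near the major histocompatibility complex from H2-D1 (chromosome 17, 35263192 to 35635943). In BTSC the longest run had 11 peaks in Nav2 (chromosome 7, 49342662 to 49440510), followed by 10 in the bicarbonate transporter gene Slc4a4 (chromosome 5, 89009651 to 89072243) and 9 each in Nckap5 on chromosome 1 and in a stretch of chromosome 2 from 128166809 to 128413452 that overlaps no protein-coding gene. Runs of 8 peaks numbered 6 in NSC, among them stretches with Ccn2 and with 21 genes on chromosome 2, and 3 in BTSC, at Mical2, at 4 genes from Spink10 and at Lipg.

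On the sex chromosomes, Xist had 1 H3K27ac peak within 3 kb in NSC and 1 in BTSC, and the Y-linked genes Kdm5d, Ddx3y, Uty and Eif2s3y had 0 peaks in all 4 lists. Chromosome X had 40 TLX peaks in NSC and 4 in BTSC, against 776 and 791 H3K27ac peaks. Chromosome Y as a whole had 0 and 1 TLX peaks and 1 and 4 H3K27ac peaks in NSC and BTSC.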
